A study of Mus musculus with 10 samples.

How the data were processed

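The series holds RNA sequencing of mouse regulatory T cells. Natural Tregs from spleen were stimulated for 24 h through the T cell receptor without or with TSLP (2 libraries each), and lung Tregs came from ovalbumin-immunized mice of a control and a Crlf2-deleted genotype (3 libraries each). Groups and replicate numbers were taken from the labels. Per the labels' protocols, libraries of T cell receptor-stimulated Tregs were made from 100 to 500 ng of RNA with a stranded total RNA kit that depletes ribosomal RNA and were read as 50 bp single ends. The kit used for the lung Tregs is not stated separately in the sources used here. The labels do not say that replicates are separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

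The deposited counts are whole reads per RefSeq transcript, 1 library per file and 31682 transcripts per library, per the file headers. The submitters' processing notes name Bowtie2 2.2.6, TopHat2 2.2.1, SAMtools 0.1.8, bedtools 2.25.0, edgeR and the mm10 build. The role of each tool, the counting tool, the strand rule and the treatment of multimapping reads are not given in the sources used here. Genes that share reads with near-identical copies, such as ribosomal protein genes with their pseudogenes, and genes that overlap others are therefore uncertain. The deposited RPKM values were made by the authors from these reads and the transcript length, scaled to a library total larger than the sum of the reads listed. Reads of a gene's transcripts overlap, so the transcript with the highest mean reads stood for each of the 23992 gene symbols, of which 4343 had several transcripts.

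Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM scaling, filterByExpr with a minimum count of 10, robust moderation, two-sided) within each comparison. Adjusted p-values are Benjamini-Hochberg, with a threshold of 0.05, and every adjusted p of a single gene comes from this test unless another tool is named. The SE of a log2 fold change was its size divided by the root of the F statistic. Levels are CPM after TMM. Gene lists (24 of biology and 17 of cell type markers, with at least 3 tested genes) were tested by camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Adjustment was over the lists of each kind within a comparison. The call on each list was repeated with an estimated correlation, with which 0 lists of biology were called in either comparison (camera, 0 and 4 lists at an unadjusted p under 0.05, fry called 7 in each). The samples, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. That rule took Crlf2, 17 key genes, the 8 largest rises and falls among genes past the threshold whose groups did not overlap and whose higher group had a mean RPKM of at least 1 (without predicted genes, receptor segments, pseudogenes and histones), and up to 4 members of each list by p. Genes outside the rule are Ly6a, Isg15 and Irf7 in the lung comparison and the genes that open the closing observations, and these were chosen after their values were seen. The result of 1 gene that the rule named is not reported here.

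Library sizes were 27237313 to 51671901 reads in spleen and 1439675 to 18349039 in lung, and the smallest lung library, control 2, gives the least precise values. Replicates were compared by chi-square over genes, and all pairs of a group differed by more than sampling noise (5.80 to 161 per degree of freedom). None was therefore treated as a second reading of the same library. Whether they are separate animals or cultures cannot be told from these values. In simulated counts with the means and sizes of these libraries, the test recovered 78 of 100 genes changed 2-fold and 100 of 100 changed 4-fold in the TSLP design (13083 genes, 4 false of 204 calls). In the lung design it recovered 25 of 100 and 68 of 100 (12471 genes, 2 false of 101 calls). The calls also include genes of a simulated list of 30 that was shifted by a log2 of 0.8, which were not counted as false. Genes were drawn independently, with the dispersion trend and without length or GC trends or an outlying library. The false calls therefore do not cover such differences between real libraries. Exact intervals on ratios of few reads cover counting error only.

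GC content came from GENCODE transcript sequences and gene coordinates from the RefSeq annotation, both of the same mouse build. For 210 symbols there was no GC value. The alternatives were the replicate number as a block, DESeq2 1.42.0, limma on log2(RPKM + 1), median-of-ratios factors, library totals alone, no filter, RPKM of at least 5, all 4 groups in 1 fit, moderation that is not robust, a 1.5-fold minimum, summed transcripts, removal of sex-linked, antigen receptor and haemoglobin genes, and leaving out each library. Added after the data were seen were the removal of a loess trend (span 0.3) on transcript length, or on length and GC content, a crossed block and an epithelial marker score as a covariate. Lists were compared with 10000 lists of other genes matched on length or GC content, each member replaced by 1 of its 100 nearest genes. Figures were drawn with matplotlib 3.10.9.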

Results

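RNA from regulatory T cells (Tregs, CD4 T cells that express the transcription factor Foxp3 and restrain immune responses) of C57BL/6J mice was sequenced in 10 libraries that fall into 4 groups. The first pair of groups held natural Tregs from spleen, cultured for 24 h with antibodies to CD3 and CD28, which stimulate the T cell receptor, without (TCR, 2 libraries) or with (TCR + TSLP, 2 libraries) thymic stromal lymphopoietin, an epithelial cytokine that signals through a receptor made of the products of Crlf2 and Il7r. The second pair held Tregs from the lungs of mice immunized with ovalbumin. These came from mice in which Cre recombinase is expressed from the Foxp3 gene (control, 3 libraries) and from mice that also carry a floxed Crlf2 (Crlf2-deleted, 3 libraries). The reads assigned to genes, with 1 transcript per gene, were 27866031 and 27237313 in the TCR libraries and 34852308 and 51671901 in the TCR + TSLP libraries. They were 7970213, 1439675 and 12179230 in the control lung libraries and 9647686, 11581598 and 18349039 in the Crlf2-deleted libraries, so that the second control library was the shallowest. Levels below are CPM after scaling for composition (normalised reads), as mean ± SD.

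Crlf2, which on the mm10 build lies on the minus strand of chromosome 5 from 109554709 to 109559128, was measured first because it is the deleted gene. It stood at 92.8, 146 and 105 normalised reads in the control lung libraries and at 9.06, 6.73 and 3.55 in the Crlf2-deleted ones (115 ± 27.7 against 6.44 ± 2.76, n = 3 each). The log2 fold change was -4.16 (SE 0.36, adjusted p = 0.00465, edgeR quasi-likelihood test). Which exons are floxed is not given in the sources used here, so the remaining reads cannot be divided between undeleted transcripts and reads of a transcript that lacks those exons. In the spleen cultures Crlf2 was at 58.7 ± 3.94 without and 43.5 ± 0.863 with TSLP (n = 2 each), a log2 fold change of -0.43 (SE 0.10, adjusted p = 0.00799). The call on this smaller difference was lost with library totals as the only scaling (log2 fold change -0.20, adjusted p = 0.105) and without TSLP library 1 or 2 (adjusted p = 0.0643 and 0.115). Its sign turned when trends on transcript length and GC content were removed (0.15, adjusted p = 0.267).

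**Figure D1:**
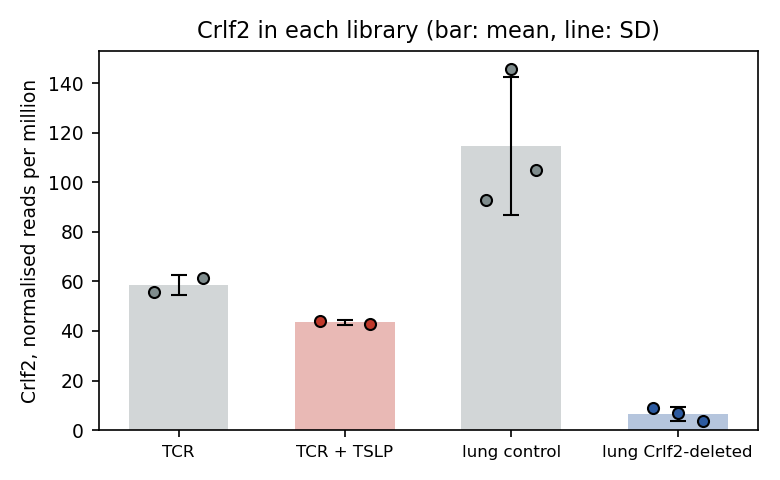
Crlf2 in normalised reads (CPM) in the 4 groups, with a point per library, a bar for the mean and a line for the SD. The 3 Crlf2-deleted libraries sit between 3.55 and 9.06, all below the control lung libraries.

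The first comparison asked what TSLP adds to T cell receptor stimulation of spleen Tregs. Some type 2 genes were higher with TSLP. Il4 went from 17.9 ± 0.733 to 39.1 ± 2.33 normalised reads (2.18-fold, log2 fold change 1.13, SE 0.10, adjusted p = 0.000213) and Il13 from 6.22 ± 0.574 to 14.9 ± 0.854 (2.40-fold, log2 1.26, SE 0.14). Ccr4 and Ccr8, chemokine receptors of type 2 helper cells and skin- or lung-homing Tregs, rose 2.89-fold (log2 1.53, SE 0.09) and 2.76-fold (log2 1.46, SE 0.12). Il5 had 4 reads over both TCR libraries and 69 over both TSLP libraries, a ratio of 9.35 with an exact 95% counting interval from 3.49 to 35.3, and passed the test at adjusted p = 0.0042. Of the 22 measured genes of the Th2 list, 10 rose, 1 fell and 11 did not pass, the same numbers that passed when adjusted over the list alone. The list was higher as a group (median log2 fold change 0.36, adjusted p = 0.00711 by camera with a preset correlation). That call was lost with a correlation estimated from the data (adjusted p = 0.652 with an estimated correlation).

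Genes that signal downstream of cytokine receptors or damp them were also higher. Among the 25 measured genes of the STAT5 and cytokine feedback list, 16 rose and 2 fell, the same as when adjusted over the list alone (median log2 fold change 0.43, adjusted p = 0.000112, adjusted p = 0.652 with an estimated correlation). Pim1, a survival kinase, rose by a log2 of 1.15 (SE 0.09), the cytokine gene Lif by 1.11 (SE 0.09) and the MAP kinase phosphatase gene Dusp5 by 1.15 (SE 0.11). Socs1, a feedback inhibitor of cytokine receptors, went from 134 to 216 normalised reads (log2 0.68, SE 0.12). Cish (log2 0.26, adjusted p = 0.0365) and the survival gene Bcl2 (log2 0.25, adjusted p = 0.0455) rose less, and the sign of Bcl2 turned to -0.05 when length and GC trends were removed. The list of the TSLP receptor and the common gamma-chain receptors also holds Jak and Stat genes. Of its 16 genes 11 rose and 1 fell, or 12 and 1 adjusted over the list alone (median 0.35, adjusted p = 0.00261, adjusted p = 0.652 with an estimated correlation). The rises included Il7r, from 27.9 to 58.1 normalised reads (log2 1.06, SE 0.12), Il2rb (log2 0.86, SE 0.09), Il2ra (log2 0.63, SE 0.09) and the kinase gene Jak2 (log2 0.70, SE 0.08).

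Genes that mark Tregs went both ways. Foxp3 was at 168 ± 15.9 without and 141 ± 10.1 with TSLP (log2 fold change -0.25, SE 0.10, adjusted p = 0.0762) and did not pass, nor did Ctla4 (0.17, adjusted p = 0.176), Ikzf2 (-0.02, adjusted p = 0.903) or Gata3 (-0.17, adjusted p = 0.266). Foxp3 passed when the trend on transcript length was removed (-0.45, adjusted p = 0.00606), and it was at 0.11 on the deposited RPKM scale (adjusted p = 0.516, limma). Of the 24 measured genes of the Treg identity list, 5 rose and 6 fell, also when adjusted over the list alone, and the list as a group was not called (adjusted p = 0.984). Tigit, an inhibitory receptor, rose by a log2 of 1.06 (SE 0.10), while Lag3, another inhibitory receptor, fell by 0.98 (SE 0.09) and Capg, an actin-capping protein, went from 457 to 229 normalised reads (SE of the log2 fold change 0.08). Of 24 tissue and effector Treg genes, 7 rose and 4 fell (adjusted p = 0.521). Irf4, a factor of effector Tregs, rose by a log2 of 0.82 (SE 0.09), and Il10, an inhibitory cytokine, by 0.58 (SE 0.13, 9.49 to 14.2 normalised reads). Lgals1 (log2 -1.12, SE 0.09) and S100a4 (log2 -1.63, SE 0.19) fell. Fold changes in this comparison followed transcript length, as given below. With that trend removed 7 of the 24 tissue and effector Treg genes rose and 3 fell (adjusted p = 0.178 by camera). Il1rl1, Areg, Ifng and Il17a had log2 fold changes of 0.47, 0.18, -0.20 and 0.32 and did not pass (adjusted p = 0.173, 0.758, 0.394 and 0.549).

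**Figure D2:**
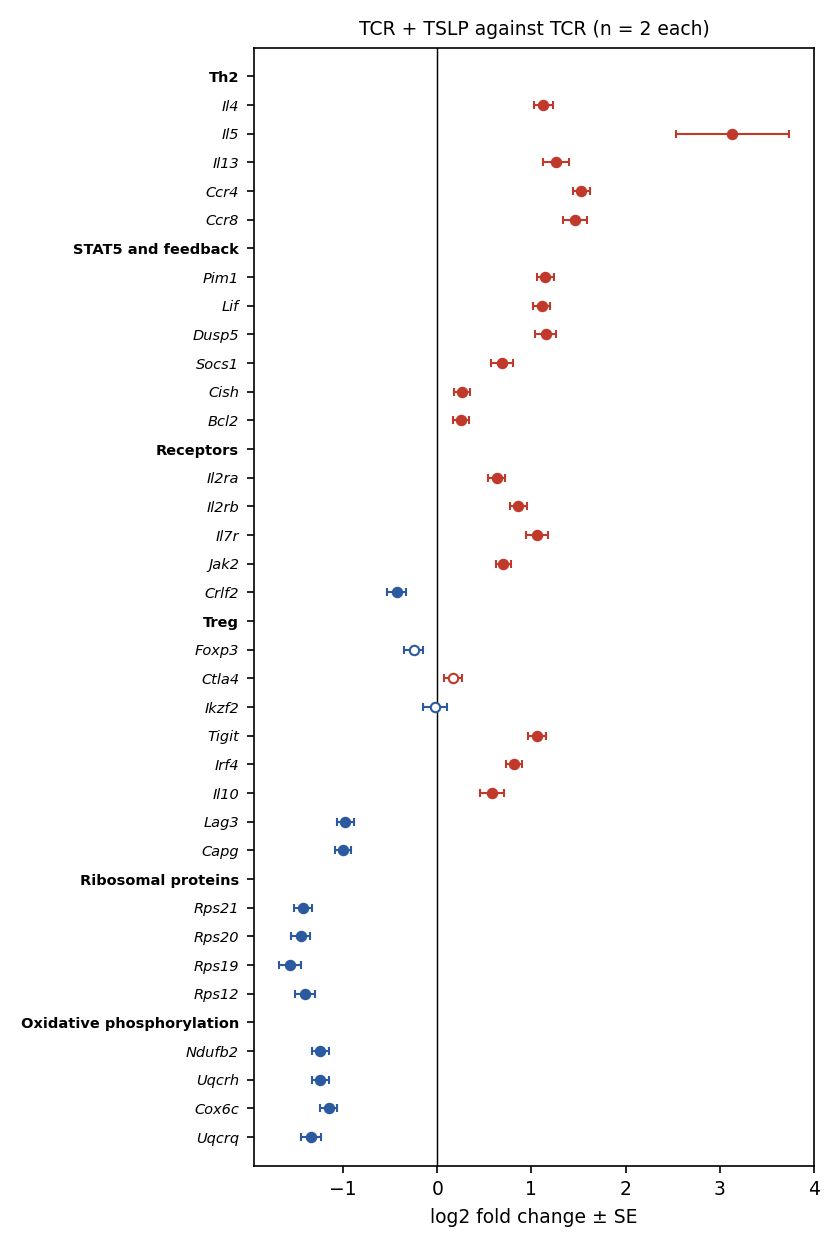
Log2 fold change of TCR + TSLP against TCR for named genes, grouped by list, with lines for the standard error from the edgeR fit (n = 2 each). Filled points passed the test and open points did not, and red stands for higher and blue for lower with TSLP. Il5 has the widest error (log2 3.13, SE 0.60), on 4 reads in the TCR libraries.

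The largest rises by the rule included Il12rb2, a chain of the interleukin-12 receptor (log2 2.13, SE 0.17), Tnfsf8, the CD30 ligand (log2 1.88, SE 0.13), Themis, a T cell receptor signalling protein (log2 1.82, SE 0.14), and Nckap1, a regulator of actin (log2 1.79, SE 0.17). The other 4 were microRNA precursor rows, Mir3572, Mir8114, Mir719 and Mir6974, with log2 fold changes of 2.39, 2.27, 2.12 and 1.86. Their rows are 86, 111, 110 and 83 bp long, and reads of overlapping transcripts were not separated from them. With 1 library left out, their log2 fold changes ran from 1.81 to 2.81, 1.33 to 7.76, 1.54 to 3.17 and 1.26 to 2.87 in the same order. Over both TCR libraries Mir3572, Mir8114 and Mir6974 had only 8, 7 and 8 reads, against 82, 64 and 54 with TSLP. The largest falls were Wnt4 (log2 -3.44, SE 0.67), Il11 (-3.30, SE 0.73), Zfp457 (-3.24, SE 0.52), Usp17la (-3.16, SE 0.37), Hyal3 (-3.14, SE 0.50), Rhox8 (-3.14, SE 0.34), Rpph1 (-3.02, SE 0.30) and Ctcfl (-2.92, SE 0.40). In each of these 8 genes the first TCR library held more reads than the second, for example 456 against 115 for Wnt4, and both TSLP libraries lay below. Without the first TCR library the log2 fold changes were -2.15, -1.79, -2.35, -2.51, -2.21, -2.60, -2.48 and -2.20 in the same order.

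Other lists called higher with TSLP were T cell activation (10 of 23 rose, 3 fell, median 0.31, adjusted p = 0.0278), cell cycle (17 of 35 rose, 3 fell, 0.29, adjusted p = 0.00829), glycolysis and hypoxia (13 of 30 rose, 3 fell, 0.21, adjusted p = 0.0172), unfolded protein response (11 of 22 rose, 4 fell, 0.32, adjusted p = 0.0412) and TGF-beta response (6 of 15 rose, 0.32, adjusted p = 0.0412). Adjusted over the list alone, the rises were 10, 18, 14, 12 and 6 and the falls 3, 4, 3, 4 and 0. With an estimated correlation none was called (adjusted p = 0.652 for T cell activation and TGF-beta response and adjusted p = 0.784 for the other 3 lists). Without TCR library 1 the calls on cell cycle, unfolded protein response and TGF-beta response were lost (adjusted p = 0.0914, 0.129 and 0.0914), and the last also without each other library (0.0598 to 0.105) and with the length trend removed (0.482). Examples were Slc7a5, an amino acid transporter (log2 0.90), Mcm4, a replication helicase subunit (log2 0.89), Egln3, an oxygen-sensing hydroxylase (log2 1.41), Sesn2, a stress-induced regulator of growth (log2 1.57), and Smad3 (log2 0.73). Members that moved against the name of the list were Birc5, a mitotic protein (log2 -0.63), and Ddit3, a stress-induced factor (log2 -0.92).

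Genes for ribosomal proteins and for the respiratory chain were lower with TSLP. Of 52 ribosomal protein genes 51 fell (median log2 fold change -1.08, adjusted p = 3.39e-23, adjusted p = 0.652 with an estimated correlation), as when adjusted over the list alone. Rps20 went from 4262 to 1558 normalised reads (log2 -1.45, SE 0.10). All symbols that start with Rps, Rpl or Rplp and a number took 22.2% and 20.9% of gene reads in the TCR libraries. With TSLP they took 12.5% and 11.96%. This set is not limited to the 52 genes and leaves out Rpsa. Of 37 oxidative phosphorylation genes 31 fell and 2 rose, or 32 and 3 adjusted over the list alone (median -0.86, adjusted p = 9.03e-11, adjusted p = 0.652 with an estimated correlation). Uqcrh (log2 -1.24), Ndufb2 (-1.24), Cox6c (-1.15) and Uqcrq (-1.34) were among them. Both medians stayed below 0 on every scale tried, at -0.71 and -0.49 on the deposited RPKM. Fold changes followed transcript length over all genes, from a median log2 of -0.999 for the 270 genes under 500 bp to 0.20 for the 3049 genes between 4000 and 8000 bp. They also followed GC content, from a median of 0.283 at 29.6 to 45.7% to -0.236 at 55.1 to 82.9%. With the length trend removed the oxidative phosphorylation median was -0.01 (adjusted p = 0.897) and the ribosomal protein median -0.28 (33 fell, 1 rose, adjusted p = 2.05e-07).

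**Figure D3:**
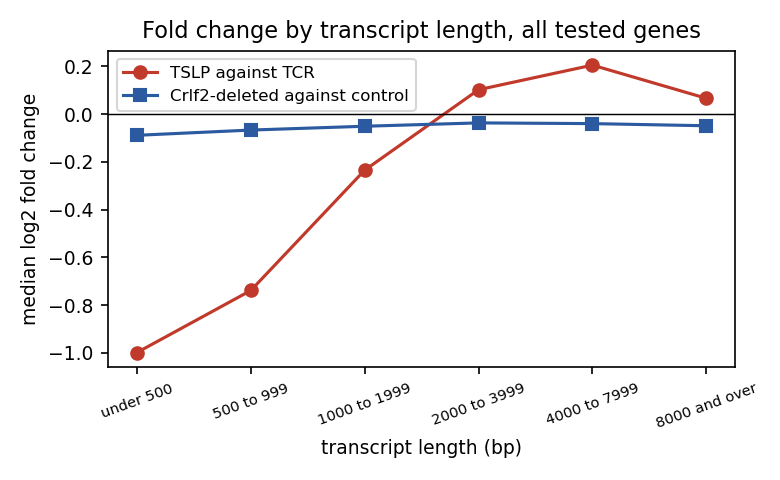
Median log2 fold change of all tested genes by transcript length in bp, for TCR + TSLP against TCR (red circles) and Crlf2-deleted against control lung Tregs (blue squares). The first comparison runs from -0.999 below 500 bp to 0.20 at 4000 to 8000 bp, while the second stays between -0.09 and -0.04.

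The remaining 14 lists were not called with TSLP. They included Th1 and cytotoxic genes (4 of 21 rose and 5 fell, adjusted p = 0.685), in which Il12rb2 rose while Nkg7 (log2 -1.29) and Xcl1 (-1.48) fell, and interferon response genes (7 of 35 rose and 9 fell, adjusted p = 0.477), in which Ifi27l2a fell by 1.71. The same held for naive and central memory genes (5 of 17 rose, 6 fell, adjusted p = 0.984), where Satb1 rose by a log2 of 1.02 and Dapl1 fell by 2.43. Adjusted p values were 0.984 for Th17, 0.181 for Tfh, 0.0779 for dissociation and immediate early, 0.938 for inhibitory receptors, 0.248 for cholesterol synthesis, 0.521 for ribosome biogenesis, 0.521 for NF-kB and TNF, 0.624 for apoptosis and 0.366 for chemokine and homing receptor genes. The dissociation list was called higher without TCR library 2 or TSLP library 2 (adjusted p = 0.0175 and 0.049) and with length and GC trends removed (0.00972). The median and the test differed in sign for the Treg identity (median -0.003), Th17 (0.09) and naive (0.10) lists, and the median (0.17) and mean (-0.08) of the inhibitory receptors did too. Among markers of other cells, the CD8 T cell list was called lower with TSLP (4 of 5 fell, median -0.81, adjusted p = 0.0386, adjusted p = 0.554 with an estimated correlation). Its member Ccl5 turned from lower to higher when the length trend was removed. Marker lists were not tested with that trend removed, so its part in this call is not known. The other marker lists that could be tested were not called (adjusted p from 0.107 to 0.862).

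In total, 6050 of 13214 genes passed the test, 2999 higher and 3051 lower with TSLP, and 3435 of them changed by at least 1.5-fold. With the length trend removed 5511 genes passed, and 4200 of the 6050 kept their call and direction. With length and GC trends removed 5212 passed, and 3650 of the 6050 kept theirs. The groups did not overlap in 9966 genes (75.4%), against 33.3% by chance. On the deposited RPKM scale the median of all genes lay 0.36 higher (log2) and 5165 genes were higher and 989 lower (limma), and with library totals alone the median lay 0.23 higher and 5059 genes were higher and 2000 lower, so directions above are relative to the composition-scaled median. Leaving out the first or the second TSLP library left 3761 or 3212 genes, and 1356 passed when all 4 groups shared an estimate of spread.

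The second comparison asked how lung Tregs of ovalbumin-immunized mice differ when they lack Crlf2. Interferon-induced genes were lower in the Crlf2-deleted Tregs. Cxcl10, an interferon-induced chemokine, went from 86.4 ± 38.0 to 8.37 ± 2.05 normalised reads (n = 3 each, log2 fold change -3.35, SE 0.36, adjusted p = 0.00925), and Mx1, an antiviral GTPase, from 42.6 ± 3.79 to 4.32 ± 3.22 (log2 -3.31, SE 0.51, adjusted p = 0.0261). Gbp2 fell by a log2 of 2.61 (SE 0.24), Rsad2 by 2.68 (SE 0.28), Oas2 by 2.78 (SE 0.46), Bst2 by 2.18 (SE 0.25) and Iigp1 by 3.18 (SE 0.37). Of the 35 measured interferon response genes 25 fell and none rose, and all 35 fell adjusted over the list alone (median log2 fold change -2.11, adjusted p = 3.13e-42, adjusted p = 0.198 with an estimated correlation). Leaving out 1 library at a time kept the median between -2.45 and -1.93. The number of list genes that passed was 5, 2 and 28 without control library 1, 2 or 3 and 0, 30 and 0 without deleted library 1, 2 or 3.

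Some genes of tissue and effector Tregs and inhibitory receptors were higher in the Crlf2-deleted Tregs. The T cell reference genes were also called higher (median 0.28, adjusted p = 0.00794, adjusted p = 0.603 with an estimated correlation). Il10 went from 43.1 to 200 normalised reads (4.83-fold, log2 2.27, SE 0.29, adjusted p = 0.016), Lag3 from 72.4 to 304 (log2 2.08, SE 0.16, adjusted p = 0.00465) and Pdcd1, which encodes the inhibitory receptor PD-1, from 312 to 1218 (log2 1.97, SE 0.32, adjusted p = 0.0354). Ccr8 rose by a log2 of 1.85 (SE 0.26), the tissue-homing receptor gene Cxcr6 by 1.67 (SE 0.24), Id2 by 1.09 (SE 0.15) and the nuclear receptor gene Pparg by 1.93 (SE 0.30). Itgb8, an integrin chain that activates TGF-beta, rose by 2.33 (SE 0.35) and belongs to the Treg identity list, not the effector list. Of 25 tissue and effector Treg genes 6 rose and 1 fell, or 13 and 3 adjusted over the list alone (median 0.48, adjusted p = 2.15e-06, adjusted p = 0.407 with an estimated correlation, adjusted p = 0.0973 by fry). The median lay 0.198 above that of the T cell reference genes. The gene that fell was Gzmb, a protease of cytotoxic granules (log2 -1.56, SE 0.16, adjusted p = 0.00762). Of 11 inhibitory receptor genes 4 rose, Lag3, Pdcd1, Klrg1 (log2 1.25, SE 0.22) and Tigit (log2 1.09, SE 0.21), against 4 rises and 1 fall adjusted over the list alone (median 0.60, adjusted p = 0.00392, adjusted p = 0.198 with an estimated correlation). Of 24 Treg identity genes 4 rose, or 5 adjusted over the list alone, and the list was not called (adjusted p = 0.162). Foxp3 was at 370 against 434 normalised reads (log2 0.23, SE 0.30, adjusted p = 0.762), and Il2ra (-0.44, adjusted p = 0.533), Ctla4 (0.61, adjusted p = 0.34) and Ikzf2 (-0.10, adjusted p = 0.897) did not pass either.

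Of the 20 measured Th2 genes 4 rose, or 8 with 4 falls adjusted over the list alone (median 0.64, adjusted p = 0.00385, adjusted p = 0.198 with an estimated correlation). These 4 were Il10, Ccr8, Pparg and Calca, which encodes the neuropeptide CGRP (log2 2.96, SE 0.39). The type 2 cytokine genes themselves did not pass, with log2 fold changes of -1.70 (SE 1.28) for Il4, -2.44 (SE 1.04) for Il5 and 0.99 (SE 0.62) for Il13 and adjusted p = 0.581, 0.307 and 0.496. Control library 3 held 348 Il4 and 216 Il5 reads, against 2 and 5 Il4 and 6 and 4 Il5 reads in the other controls. Without it the log2 fold changes were 1.59 and 0.01 (adjusted p = 0.457 and 0.997). Gata3 (1.01, adjusted p = 0.0897), Il1rl1 (0.62, adjusted p = 0.312), Areg (0.73, adjusted p = 0.18), Ifng (-0.53, adjusted p = 0.731) and Il17a (-2.38, adjusted p = 0.241) did not pass. Markers of group 2 innate lymphoid cells, some of which Tregs share, summed to 2470 ± 322 normalised reads in the Crlf2-deleted libraries and 1549 ± 369 in the controls, higher in every deleted library, and that list was called (3 of 10 rose, adjusted p = 0.000134, adjusted p = 0.581 with an estimated correlation). Its risen members were Calca, Klrg1 and Il7r, and Ly6a fell by 1.59.

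Of 25 STAT5 and cytokine feedback genes 3 fell in the Crlf2-deleted Tregs and 22 did not pass, or 6 fell and 1 rose adjusted over the list alone. The list was called lower (median -0.36, adjusted p = 0.000265, adjusted p = 0.198 with an estimated correlation). The median lay below that of all genes on each scale tried, at -0.36 against -0.04 here, -0.18 against 0.14 with library totals alone and 0.06 against 0.375 on the deposited RPKM. The fallen genes were Gzmb, Socs1 (log2 -1.12, SE 0.18, 373 to 171 normalised reads) and Socs3, another feedback inhibitor (log2 -0.68, SE 0.13). Cish (-0.15, adjusted p = 0.801) and Bcl2 (-0.71, adjusted p = 0.539) did not pass. Of the 16 genes of the receptor list, which also holds Jak and Stat genes, Crlf2 fell and Il7r rose (log2 1.29, SE 0.17). Adjusted over the list alone there were 1 rise and 2 falls, and the list was not called (adjusted p = 0.396).

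**Figure D4:**
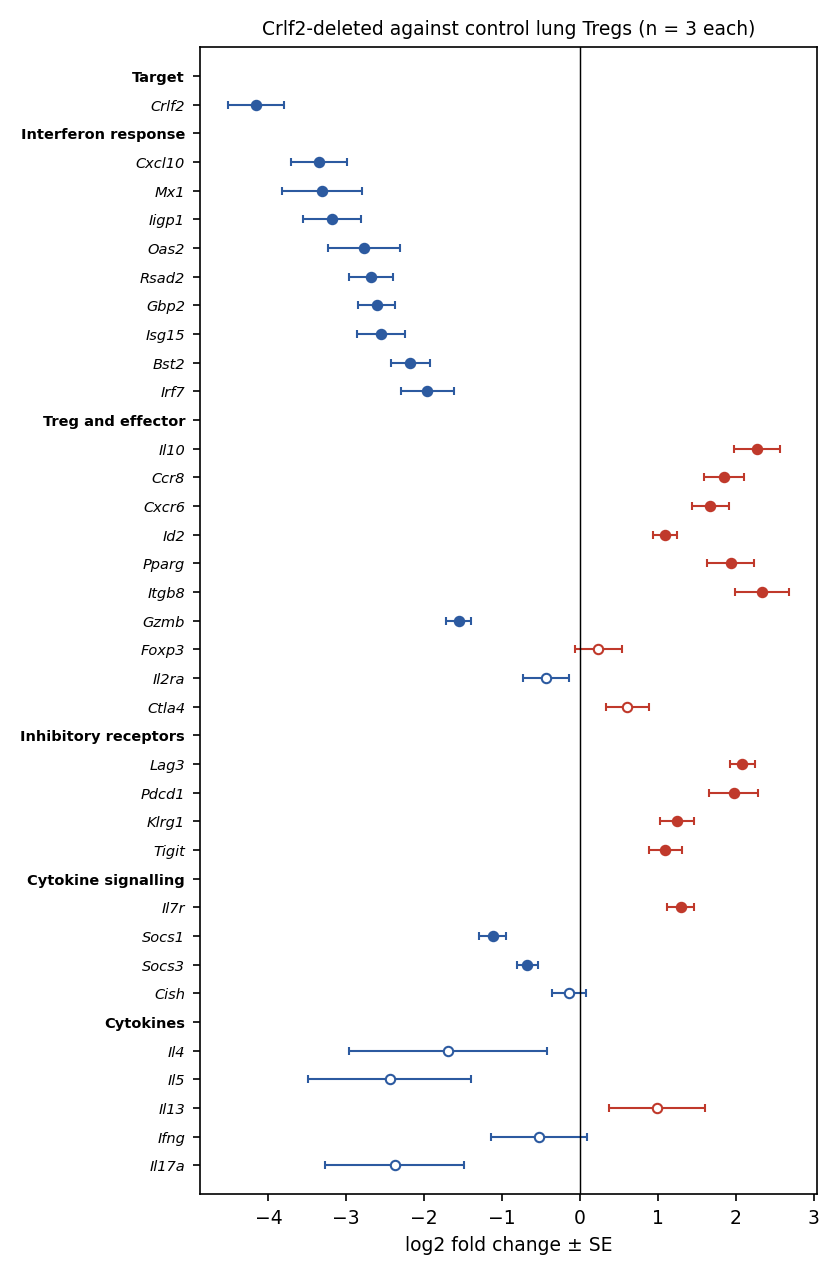
Log2 fold change of Crlf2-deleted against control lung Tregs for named genes, with lines for the standard error from the edgeR fit (n = 3 each). Filled points passed the test and open points did not, and red stands for higher and blue for lower in the Crlf2-deleted Tregs. The 9 interferon-induced genes, of which Iigp1 is outside the fixed list, lie between -3.35 and -1.96.

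The largest rises by the rule were Esm1 (2.19 ± 1.09 to 27.9 ± 5.09 normalised reads, log2 3.87, SE 0.40), Gfra4, a receptor of glial-derived ligands (log2 3.85, SE 0.60), Col18a1, a basement membrane collagen (log2 3.52, SE 0.35), Scg5 (log2 3.49, SE 0.52), Calca, Cib2 (log2 2.84, SE 0.24), Wisp1 (log2 2.81, SE 0.55) and Vipr2, a receptor of vasoactive intestinal peptide (log2 2.81, SE 0.53). After Crlf2, the largest falls were Tnp2 (log2 -3.44), Cxcl10, Mx1, Iigp1, Lrrc25 (-3.15), the microRNA precursor row Mir6381 (-2.79) and Oas2.

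Further lists called lower were Th1 and cytotoxic (1 of 20 fell, median -0.82, adjusted p = 0.00512, adjusted p = 0.442 with an estimated correlation), naive and central memory (1 rose and 1 fell of 17, -0.59, adjusted p = 0.000593, adjusted p = 0.423 with an estimated correlation) and cell cycle (1 of 35 fell, -0.59, adjusted p = 3.31e-07, adjusted p = 0.219 with an estimated correlation). Birc5 fell by a log2 of 1.17 (SE 0.23), and adjusted over the list alone 4, 9 and 3 genes of these lists fell and 1, 1 and 0 rose. Ribosome biogenesis (median -0.24, adjusted p = 0.0111, adjusted p = 0.219 with an estimated correlation) and ribosomal protein genes (-0.09, adjusted p = 0.0129, adjusted p = 0.593 with an estimated correlation) were called lower with 0 members past the test, and their medians were 0.20 and 0.33 on the deposited RPKM scale, where that of all genes was 0.375. Dissociation and immediate early genes were called higher (1 rose and 1 fell of 22, median 0.14, adjusted p = 0.0387, adjusted p = 0.593 with an estimated correlation), with the heat shock gene Hsph1 risen from 81.6 to 162 normalised reads. The Th1 call was lost without control library 3 (adjusted p = 0.147) and the dissociation call without control library 1, control library 2 or deleted library 1 (0.248, 0.259 and 0.0565). The ribosomal protein call was lost without control library 2 or deleted library 1 or 2 (0.0813, 0.15 and 0.117), and the ribosome biogenesis call without deleted library 2 (0.0856).

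The 11 other lists not called and not yet given had adjusted p = 0.203 for Th17, 0.511 for Tfh, 0.296 for T cell activation, 0.511 for cholesterol synthesis, 0.529 for glycolysis and hypoxia, 0.176 for oxidative phosphorylation, 0.296 for the unfolded protein response, 0.209 for NF-kB and TNF, 0.93 for apoptosis, 0.196 for chemokine and homing receptors and 0.176 for TGF-beta response. In the Tfh list Tox2 rose (log2 1.61) and Bcl6 fell (-1.07), and in the NF-kB list Nfkb1 (1.12) and Tnfaip3 (0.57) rose and Bcl3 (-0.83) fell. Among the homing receptors Gpr183 fell by 1.04. For the apoptosis list the median (-0.20) and the test differed in sign, as did the median (0.004) and mean (-0.01) for glycolysis.

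Other cells contributed unevenly to the lung libraries. Epithelial markers summed to 80960, 16910 and 25190 normalised reads in the control libraries and 15120, 18400 and 2452 in the Crlf2-deleted ones, and erythroid markers to 1821, 6759 and 166900 against 2672, 2261 and 1842. Dendritic cell markers summed to 695, 734 and 5254 against 640, 794 and 667, so the difference in both of these lay in control library 3. That library also had the highest B cell (482), macrophage (10720) and neutrophil (830) sums. Macrophage sums were nonetheless higher in every Crlf2-deleted library (3440, 3683 and 3820) than in control libraries 1 and 2 (970 and 1544). The same held for NK cell (192.8, 220.5 and 221 against 101.2 and 118.4), fibroblast (199.8, 300 and 213.6 against 42.79 and 72.53) and CD8 T cell sums. It did not hold for B cell, dendritic cell, neutrophil or epithelial sums. The epithelial (median -1.73, adjusted p = 7.26e-05), dendritic cell (-1.72, adjusted p = 0.0283) and erythroid (-4.72, adjusted p = 0.00935) lists were called lower in the Crlf2-deleted libraries, and the T cell reference list was called higher (0.28, adjusted p = 0.00794), each with adjusted p = 0.603 with an estimated correlation. The B cell list was not called (median -2.27, adjusted p = 0.0706), nor were the other marker lists that could be tested, apart from the innate lymphoid list given above (adjusted p from 0.0833 to 0.739). With the epithelial marker score as a covariate 0 genes passed (edgeR, 814 at an unadjusted p under 0.05), and Crlf2 had a log2 fold change of -3.85 (SE 0.47, adjusted p = 0.17). The median of the interferon list was then -1.78 and that of the tissue and effector list 0.32. The median SE of their genes went from 0.31 to 0.42 and from 0.22 to 0.32, and 11 lists were called, 10 of them shared.

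In total, 227 of 12717 genes passed in the lung comparison, 98 higher and 129 lower in the Crlf2-deleted Tregs, with 2800 genes (22.0%) whose groups did not overlap against 10% by chance. The count fell to 33, 22, 4, 124 and 7 without control library 1, control library 2 or deleted library 1, 2 or 3, and it rose to 532 without control library 3. DESeq2 called 938 genes, a fit with the replicate number as a block 121 and one with transcripts of a gene summed 134. On the deposited RPKM scale, where the median of all genes lay 0.42 higher (log2), limma called 1338 higher and 117 lower, against 137 and 57 with library totals alone (shift 0.18).

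The third question joined the comparisons, since gain of the cytokine and loss of its receptor would move a direct target in opposite directions. The 2917 genes that rose with TSLP and were measured in lung had a median log2 fold change of -0.04 in Crlf2-deleted Tregs, the same as all genes, and the set was not called (p = 0.512 by camera, p = 0.586 with an estimated correlation). The 2763 genes that fell with TSLP had a median of -0.03 (p = 0.971 by camera, p = 0.981 with an estimated correlation). Of 115 genes that passed in both comparisons, 56 moved in opposite and 59 in the same direction (Fisher's exact test, two-sided, p = 0.849). Socs1, Socs3 and Gzmb rose with TSLP and fell in Crlf2-deleted Tregs, whereas Il10, Il7r, Ccr8, Tigit and Id2 rose in both comparisons and Lag3 fell with TSLP and rose in lung. These 9 genes were chosen after their values were seen. Across 11886 genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.013 and a Spearman rho of -0.012.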

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

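Tests chosen only after results were seen are the removal of length and GC trends, the crossed block and the epithelial covariate. The rest were fixed beforehand. The cause of each change below was not tested, except that a stricter filter, a fold minimum or a left-out library uses fewer genes or samples. With TSLP, the count of 6050 genes became 3622 with RPKM of at least 5, 3435 with a 1.5-fold minimum and 1356 with all 4 groups in 1 fit, and 3212 to 8624 when 1 library was left out (3761 without TSLP library 1, 3212 without TSLP library 2). Where 1 library remained in a group, it was assumed to vary like the other group. With the length trend removed 5511 genes passed, but only 4200 of the 6050 kept their call and direction. With length and GC trends removed these numbers were 5212 and 3650. The Crlf2 log2 fold change of -0.43 was -0.058 with limma on RPKM, -0.20 with library totals, -0.39 with all 4 groups, -0.15 with the length trend removed and 0.15 with length and GC trends removed, all without a call, and -0.50 to -0.34 when 1 library was left out.

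Of 118 other genes named for TSLP, 9 changed sign in some alternative, and 5 of these (Bcl2, Ccl5, Batf, Bst2 and Bax) had passed the test. With length and GC trends removed Bcl2 was at -0.049, Ccl5 at 0.29, Batf at 0.32, Bst2 at 0.11 and Bax at 0.32, and with the length trend alone removed Ccl5 was at 0.22, Batf at 0.17, Bax at 0.10 and Ifng at 0.17. With limma on RPKM Foxp3 was at 0.11, Ikzf2 at 0.25, Gata3 at 0.20 and Ifng at 0.10, and with library totals Ikzf2 was at 0.21, Gata3 at 0.058 and Ifng at 0.025. Ikzf2 was also at 0.021 with no filter and 0.022 with all 4 groups. When 1 library was left out, Ikzf2 ranged from -0.16 to 0.16 and Gata3 from -0.31 to 0.011. All 4 groups in 1 fit ended the call of 43 of these genes. Of 10 lists called, 0 held with an estimated correlation (camera, 0 at an unadjusted p under 0.05, 7 with fry) and 7 to 10 were called when 1 library was left out. The fry test ended the calls on cell cycle, glycolysis and unfolded protein response (adjusted p = 0.163, 0.118 and 0.152). Of the lists not called, dissociation and immediate early gained a call with length and GC trends removed (adjusted p = 0.00972) and without TCR library 2 (0.0175) or TSLP library 2 (0.049), and 6 others changed direction without a call. With length and GC trends removed these were Treg identity (adjusted p = 0.836), Th1 and cytotoxic (0.297), Th17 (0.779), inhibitory receptors (0.631), NF-kB and TNF (0.534) and apoptosis (0.936). With the length trend alone they were Treg identity (0.897), Th1 (0.272) and Th17 (0.698), with the replicate block Th1 and inhibitory receptors (both 0.996) and with fry inhibitory receptors (0.195). When 1 library was left out, adjusted p ran from 0.909 to 1 for Treg identity, 0.813 to 1 for Th1, 0.896 to 1 for Th17 and 0.604 to 1 for inhibitory receptors.

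In lung, the count of 227 genes became 121 with the replicate block, 938 with DESeq2, 1455 with limma on RPKM, 873 with all 4 groups in 1 fit, 134 with transcripts summed and 0 with the epithelial covariate (edgeR, 814 at an unadjusted p under 0.05). It ranged from 4 to 532 when 1 library was left out, with 33, 22 and 532 without control library 1, 2 or 3 and 4, 124 and 7 without deleted library 1, 2 or 3. Of the 82 genes named, 54, 55, 64, 32 and 63 lost the call without control 1, control 2, deleted 1, deleted 2 or deleted 3. None of the 66 that had passed changed sign, but 8 of the 16 that had not did. With limma on RPKM Il2ra was at 0.049, Ikzf2 at 0.31 and Cish at 0.32, with library totals Ikzf2 at 0.049 and Cish at 0.011, and with length and GC trends removed Ikzf2 at 0.024. When 1 library was left out, Foxp3 ranged from -0.066 to 0.47, Ikzf2 from -0.40 to 0.094, Cish from -0.38 to 0.025, Bcl2 from -0.98 to 0.11, Il4 from -2.30 to 1.59, Il5 from -3.00 to 0.011 and Ifng from -0.97 to 0.19. All of these but Ikzf2 and Cish turned without control library 3. Crlf2 kept its call in every alternative except the epithelial covariate (log2 fold change -3.85, adjusted p = 0.17), with -4.47 to -3.84 when 1 library was left out. With that covariate sizes were smaller and errors larger. The median of the interferon list was -1.778 (main -2.106, median SE 0.423 against 0.31) and that of the tissue and effector list 0.32 (main 0.483, SE 0.315 against 0.222), on 3 residual degrees of freedom instead of 4, and 11 lists were called, 10 of them shared. Of 11 lists called, 0 held with an estimated correlation (camera, 4 at an unadjusted p under 0.05) and fry called 7, 5 of them shared. Calls lost with fry were tissue and effector Treg (adjusted p = 0.0973), Th1 and cytotoxic (0.187) and naive and central memory (0.176). Also lost were dissociation and immediate early (0.464), ribosomal proteins (0.187) and ribosome biogenesis (0.0549). Calls were gained by oxidative phosphorylation with the covariate (adjusted p = 0.0265) and without deleted library 3 (0.0163), by Tfh and NF-kB with fry (0.0342 and 0.0381), by Treg identity without control 1 or 2 (0.0416 and 0.00707), by TGF-beta response without control 2 (0.0236) and by the receptors and the homing receptors without control 3 (0.0467 and 0.043). Lists not called in lung changed direction with the covariate (glycolysis, adjusted p = 0.937, and apoptosis, 0.742), with fry (apoptosis, 0.694) and when 1 library was left out. There the adjusted p ran from 0.651 to 0.901 for apoptosis, 0.0467 to 0.826 for the receptors, 0.00707 to 0.496 for Treg identity, 0.234 to 0.865 for cholesterol synthesis and 0.156 to 0.751 for the unfolded protein response. The tests of TSLP-responsive genes in Crlf2-deleted Tregs gave no call in any alternative (p from 0.15 to 0.988 for the genes that rose and 0.083 to 0.984 for those that fell). Both sets changed direction when 1 library was left out (p from 0.15 to 0.988 and 0.341 to 0.984), and the second also with fry (0.844), the 200 genes of lowest p (0.083) and length and GC trends removed (0.901).

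The labels do not say whether same-numbered libraries were paired. Deviations of same-numbered libraries correlated at -0.125 in spleen and 0.084, -0.148 and -0.045 in lung. These few values cannot decide it, since 2 libraries per group give only 1 distinct value in spleen. The replicate block gave 5817 genes with TSLP and the crossed block 7107, and of the lists the replicate block ended only the call on TGF-beta response (adjusted p = 0.0869). Pseudocounts of other sizes were not run, since they applied only to a main test on RPKM. In lung, control library 2 held 1439675 reads, the fewest, and the simulated lung design recovered 25 of 100 genes changed 2-fold.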

Other observations

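Tests chosen only after the results were seen are all those below except the interferon medians with 1 library left out and the counts over other splits of the lung libraries, and the genes of this and the next paragraph were chosen after their values were seen. These are single genes, and no list of genes of antigen processing, glucocorticoid response or the TNF family was fixed or tested. In Crlf2-deleted lung Tregs Tap1, a peptide transporter, fell by 0.99 on the log2 scale (SE 0.18, 609 to 306 normalised reads), and its partner gene Tapbp fell by 0.71 (SE 0.13). The immunoproteasome genes Psmb9 and Psmb10 fell by 0.75 (SE 0.14) and 0.81 (SE 0.14), the proteasome activator gene Psme2 fell by 0.74 (SE 0.14) and Cd274, which encodes the ligand of PD-1, fell by 1.04 (SE 0.20). All 6 had non-overlapping groups and adjusted p between 0.0337 and 0.0459 in edgeR's quasi-likelihood test (n = 3 each). Nr3c1, which encodes the glucocorticoid receptor, rose by a log2 of 0.94 (SE 0.14, adjusted p = 0.0232), and Tsc22d3 and Ddit4, known glucocorticoid-induced genes, by 0.92 (SE 0.15, 460 to 873 normalised reads) and 0.93 (SE 0.17). Ramp1, a subunit of the receptor for the peptide that Calca encodes, rose by 1.29 (SE 0.22, 98.5 to 242 normalised reads). Nmur1 and Il17rb, markers of group 2 innate lymphoid cells, were at 3.88 against 19.5 and 12.8 against 31.6 normalised reads and did not pass (adjusted p = 0.0777 and 0.0935).

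In spleen Tregs 3 genes rose with TSLP at low levels. Cd40lg went from 5.25 ± 1.61 to 13.7 ± 1.22 normalised reads (log2 fold change 1.39, SE 0.20, n = 2 each), Tnfrsf8, which encodes CD30, from 5.65 to 11.6 (log2 1.04, SE 0.20), and Tnfsf4, which encodes the OX40 ligand, from 3.86 to 9.81 (log2 1.35, SE 0.35). The nuclear RNA Malat1 was at 828 and 336 in the TCR libraries and 199.9 ± 2.65 with TSLP (log2 -1.54, adjusted p = 0.0238), Lars2 at 10770 and 5648 against 2654 and 2664 (log2 -1.63, adjusted p = 0.00702) and Akap5 at 170 and 73.8 against 25.5 and 25.9 (adjusted p = 0.00554).

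The first pattern weighed is the lower level of ribosomal protein genes with TSLP. Their median log2 fold change lay 0.31 below that of lists of other genes matched on transcript length (difference -0.313, matched lists -0.929 to -0.567, 4 of 10000 as low). It lay 1.05 below lists matched on GC content (difference -1.047), which argues against GC content alone. The length-matched lists themselves had a median of -0.766. The list median of -1.08 became -0.276 with the length trend removed and -0.24 with length and GC trends removed. Much of the fall thus went with length. A part beyond length is less sure, since the limit of 0.3 was set after results were seen and expression level was not matched. On the deposited RPKM the median ratio was -0.709, with 48 of 52 genes lower in both TSLP libraries. That scale moved all genes about alike (0.361 at the median of all genes, 0.37 at that of the list). The fall relative to other genes could therefore not depend on it, and the value shows only that the list was lower on this scale too. For oxidative phosphorylation genes the difference from length-matched lists was -0.093, so a length trend between the groups may account for that list. What made the length trend, whether RNA or library preparation or an effect of TSLP on short transcripts, stays open, and reads shared with ribosomal protein pseudogenes could not be separated.

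The second pattern is the lower level of interferon response genes in Crlf2-deleted lung Tregs. With 1 library left out at a time the list median stayed at -1.926 or below, which argues against a single library as its source. Of the marker lists of other cells, 2 were higher in every control library, mast cell and basophil (125 ± 188 against 10.9 ± 1.28 normalised reads) and endothelial cell (144 ± 29.2 against 98.3 ± 7.61), and the first had too few tested genes while the second was not called (adjusted p = 0.377). That count does not decide whether RNA of other cells may have contributed, and how the Tregs were isolated from lung is not given in the sources used here. An effect of the deletion and a difference in exposure between the mice stay open as well.

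The third pattern is the higher level of the tissue and effector Treg list in Crlf2-deleted lung Tregs, in which 6 of 25 genes rose and Gzmb fell. The 25 measured genes (log2 fold changes of -1.56 to 2.27) lay only 0.198 above the T cell reference genes in median. A lower share of T cells in the controls may therefore account for part of the shift of the list as a whole. The T cell reference sums were 4791, 5005 and 3362 normalised reads in the controls and 5581, 4924 and 5773 in the deleted libraries. The lowest was in control library 3, without which the list median was still 0.429. The Treg identity list, also of genes of these cells, had a median of only 0.038. With 1 library left out the median of the list was 0.429 or more, which argues against a single library as the source of that median. Calls on single genes depended on the libraries, since 0 of the 25 rose without control library 1, deleted library 1 or deleted library 3, and 2 without control library 2. Whether the deletion raised these genes within cells or the share of cells that express them is untested.

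The 6 lung libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In 1 of the 10 splits, the real one, 227 genes passed, and the highest other split had 0 (edgeR, 280 to 658 at an unadjusted p under 0.05). Likewise 1 split, the real one, had 11 lists called, and the other splits had 2 to 8. Other splits called the interferon list at adjusted p = 2.08e-06, 8.35e-19, 3.76e-06, 3.93e-07 and 6.5e-09 (camera with a preset correlation). In the remaining splits it was not called (adjusted p from 0.0535 to 0.149). Each other split set 2 libraries of a genotype and 1 of the other against the reverse and so kept part of the genotype difference. The set raised by TSLP had as low a p as the real 0.512 in 9 of the 10 splits, and the lowest other p was 0.00267.

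A hypothesis of its own was that loss of TSLP signalling reverses the STAT5 feedback genes that TSLP raises. Across the 25 genes of that list, which are not independent replicates, the log2 fold changes of the comparisons had a Pearson r of -0.404 and a Spearman rho of -0.257 (permutation p of r = 0.0442, two-sided, 100000 resamples). A threshold of r alone was set first, and the comparison with the other lists was added after r was seen. Adjusted over the 24 lists the p was 0.231, 4 of the 24 lists had an r as low (range -0.493 to 0.552), and with length and GC trends removed r was -0.312. The hypothesis is therefore left undecided.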
